A study of Homo sapiens with 36 samples.

How the data were processed

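The study profiled RNA of primary human astrocytes, glial cells of the brain kept in culture, after siRNA against ADAR1 (knockdown) or a scramble siRNA with no intended target. ADAR1, encoded by ADAR, converts adenosine to inosine in double-stranded RNA. Per the labels' protocols, RNA bound by J2, an antibody against double-stranded RNA, was pulled down with a commercial RNA immunoprecipitation kit (RIP), and input RNA was extracted beside it. No pull-down with a control antibody is among the libraries. RNA called J2-bound below is therefore that of the RIP libraries, any unspecific carry-over included. The labels give 3 library versions, each with 12 libraries in 4 groups of 3 replicates: input scramble, input knockdown, RIP scramble and RIP knockdown. Per the labels, version 2 used polyadenylated RNA and versions 1 and 3 used total RNA. The protocol names an abundance-based and a probe-based depletion of ribosomal RNA beside the polyadenylated RNA kit, and which depletion belongs to version 1 or to version 3 is not given in the sources used here.

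The deposited values are a signal per gene or repeat subfamily: the authors divided reads by 1 size factor per library. This was read from the values themselves, since 100% of them were whole multiples of the smallest value of their library within 0.001 reads. The size factors so recovered matched median-of-ratios factors recomputed over the 12 libraries of a version. Per the submitters' processing notes, fastp 0.20.0, STAR 2.7.3a, DESeq2 1.30.1 and the hg38 build are named, without their role or order. The read counter, its strand setting, its treatment of reads with several positions and its annotation are not given in the sources used here. Reads of repeat subfamilies, paralogs and overlapping genes may therefore be shared. Each version had its own table of 27665 features, 26485 genes and 1180 repeat subfamilies, and the 3 tables were normalized separately. Comparisons were tested only within a version. Values below are called normalized reads.

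Gene symbols were matched to current names, 23758 by symbol and 1562 by 1 older symbol, and 1165 had no match. The genes are named as the tables name them, so RIGI appears as DDX58, NORAD as LINC00657 and histone genes under HIST names. Depth was taken as the sum of the whole reads recovered per library. Reads of a kit without stated molecular identifiers are not independent molecules, so bounds from counts cover counting error only. Libraries of 1 group differed by far more than sampling noise (chi-square per degree of freedom of at least 3.01), so all libraries were kept as separate samples.

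Tests were run with limma 3.58.1 in R 4.3.3 (trend and robust settings) on log2 of normalized reads plus a pseudocount of 1, and fold changes are on that scale, which understates the change of low genes. Genes and repeat subfamilies with at least 10 normalized reads in at least 3 of the 12 libraries of a version were tested. A model with 4 group means gave 5 comparisons: knockdown against scramble in input, knockdown against scramble in RIP, RIP against input in scramble cells, RIP against input in knockdown cells, and the interaction, which is the knockdown effect in RIP minus that in input. Adjusted p is Benjamini-Hochberg over all features tested, with 0.05 as the threshold, and errors of log2 fold changes are standard errors (SE, n = 3 libraries per group). All p-values are two-sided. The 4 groups shared 1 estimate of spread per feature, so SE and p of RIP comparisons also drew on input libraries, and the reverse. Chi-square per degree of freedom between libraries of a group was 13.8 to 43.6 in RIP and 3.01 to 10.5 in input of version 1. It was 41.2 to 253 and 6.04 to 15.1 in version 2, and the ranges overlapped in version 3. Where RIP spreads more, its p-values come out too small and those of input too large. A feature was alike in 3 versions when it passed in the same direction in each of them. A fold against a group with no read in any library was taken against 3 counts per library and is written "at least". Where a group held only 1 to 3 counts in a library, levels are given without a fold.

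Gene lists were fixed before the data were examined, as were the tests and the rule for named genes. The lists were interferon-stimulated genes, dsRNA sensing and signalling, interferons and inflammatory mediators, integrated stress response genes, KRAB-type and other ZNF-numbered zinc finger genes, transcripts known for inverted Alu copies in the 3-prime UTR, recoding or intronic ADAR editing targets, nuclear long noncoding RNAs, cytosolic ribosomal protein genes, replication-dependent histone genes, snoRNA and scaRNA genes, structured small noncoding RNAs, p53 and apoptosis genes, cell cycle genes, and markers of astrocytes, reactive astrocytes, neurons, oligodendrocyte lineage, endothelium, fibroblasts and mural cells, and microglia and macrophages. A list of mitochondrial genome transcripts had none of its 15 members in the tables, and fewer than 5 microglia and macrophage markers could be tested, so neither was tested. Lists were tested with camera of limma at a preset correlation of 0.01 between genes, with adjusted p over the lists of a comparison. The alternatives were a correlation estimated from the data and fry. Lists of 11 repeat families were added after the data were seen and form a family of tests of their own.

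Named genes are the 10 rising and 10 falling features alike in 3 versions that rank highest by the smallest of their 3 absolute log2 fold changes (filled up from those passing in 2 versions), the 3 largest of each direction per version whose groups did not overlap, ADAR, ADARB1 and ADARB2, and 2 to 4 members per list with the smallest adjusted p in any version. Pseudogenes, unnamed genes and overlapping genes could be passed over for the next in rank, and fewer than the rule allows are printed. AluSx1 in RIP against input in scramble cells, and BATF2, IFIT2, SLC25A47 and AluSx1 in the interaction, were chosen after their values were seen.

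Every count, the ADAR values and the named genes were recomputed with a pseudocount of 4, with no filter, with library totals set equal, with only the groups compared in the model, with the replicate number as a block, with library weights (arrayWeights), with edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, and without each library in turn. After the data were seen, version 3 was also run without its 3 shallowest RIP libraries (RIP scramble 3, RIP knockdown 1 and RIP knockdown 2), which leaves 1 RIP knockdown library, taken to vary like the other groups. The limma step was tested on simulated negative binomial counts with the means, size factors and dispersions of these features, 200 of them changed. For knockdown against scramble in input it recovered 15.3% to 79.0% of genes changed 2-fold and 51.0% to 96.0% of those changed 4-fold over the 3 versions, with 5 to 8 false calls. For knockdown against scramble in RIP it recovered 23.5% to 76% and 61.6% to 97.9%, with 4 to 23 false calls. For the interaction it recovered 4% to 69.7% and 35% to 90.9%, with 1 to 9 false calls. The simulation gave each feature 1 dispersion in all 12 libraries of a version. It therefore cannot show false calls in RIP or lost calls in input that arise where RIP spreads more than input. Data preparation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib. The lists drawn were chosen after their values were seen, and snoRNA and scaRNA genes, whose median in versions 2 and 3 changes sign under another scaling, were left out of the figure of RIP against input.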

Results

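Double-stranded RNA was pulled down with the J2 antibody from primary human astrocytes treated with siRNA against ADAR1 or with scramble siRNA, and was sequenced beside input RNA in 3 library versions of 12 libraries each. Ribosomal RNA took 41.5 ± 3.53% of normalized reads in version 1 RIP libraries (mean ± SD, n = 6) and at most 0.267% in version 1 input. In version 3 ribosomal RNA took 8.45% to 17.9% of RIP scramble and 18.3% to 25.4% of RIP knockdown reads (means 11.9% and 21.6%, n = 3 each), 2 groups that did not overlap, a difference that was not tested. Version 3 input held at most 0.225%, and in version 2, made from polyadenylated RNA, all 12 libraries held at most 0.119%. Repeat subfamilies took 16.6 ± 5.21% of RIP and 6.45 ± 0.342% of input reads in version 2, and 24.8 ± 3.77% of RIP and 15.4 ± 1.96% of input reads in version 3. In version 1 repeats took 34.4 ± 3.63% of RIP and 35.5 ± 1.28% of input reads. The Alu subfamily AluSx1 alone took 6.07 ± 4.54% of version 2 RIP knockdown reads (1.33% to 10.4%, n = 3), against 1.25 ± 0.551% in RIP scramble. The tables were normalized separately, so levels are set beside each other across versions only as description.

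Depth was 18.9 to 26.1 M reads in version 1 and 37.8 to 53.8 M in version 2. Version 3 input libraries held 39.3 to 49.4 M reads and RIP libraries 8.76 to 25.6 M, and the 3 shallowest were RIP knockdown 2 (8.76 M), RIP scramble 3 (9.21 M) and RIP knockdown 1 (10.4 M). Whether replicates came from separate cultures is not given in the sources used here, so p-values measure only the spread between these samples, which may be technical. The same holds between the versions, whose starting RNA may be shared.

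**Figure D1:**
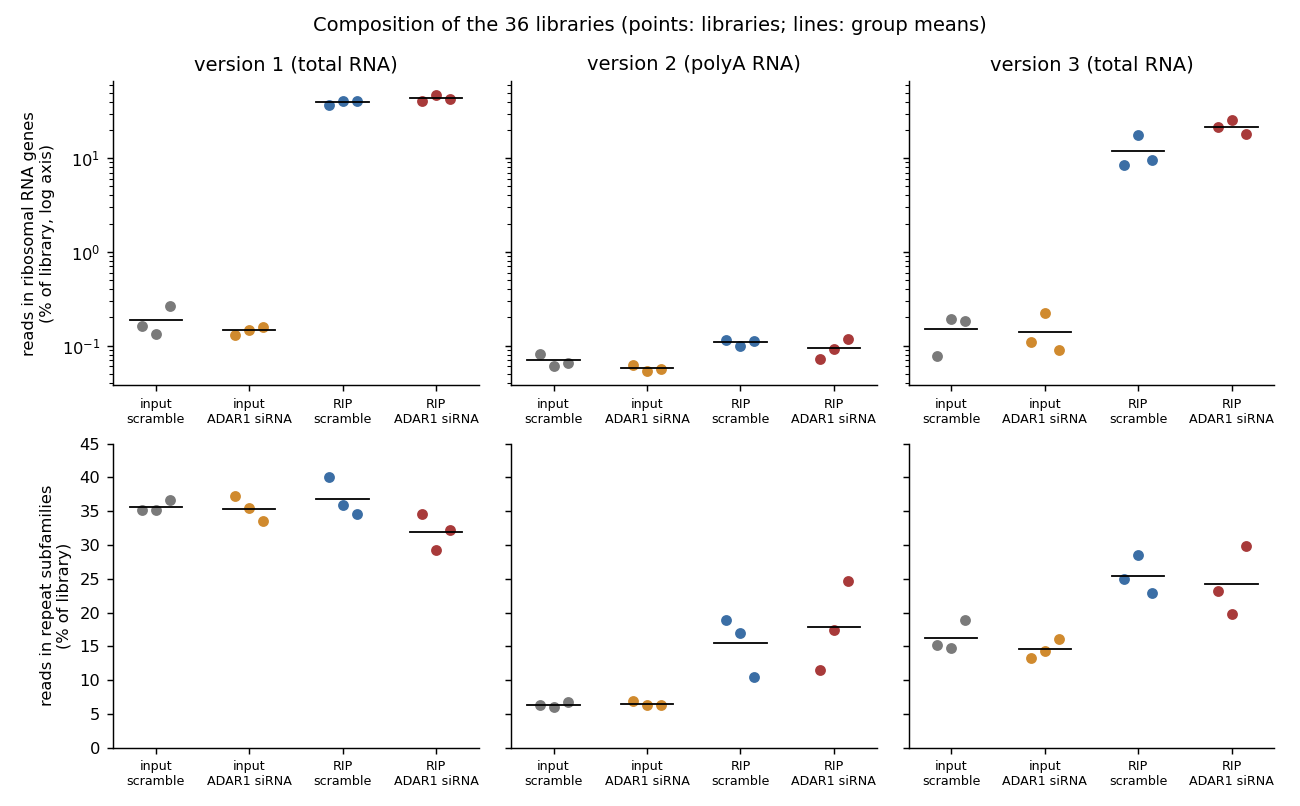
Share of normalized reads on ribosomal RNA genes (top, log axis) and on repeat subfamilies (bottom) in each library of the 3 versions. Points are libraries and lines are means of 3.

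ADAR, the siRNA target, fell after knockdown in both fractions of all 3 versions. In input its level went from 13487 ± 345 to 5101 ± 172 normalized reads in version 1, from 46375 ± 865 to 17248 ± 1028 in version 2 and from 25319 ± 2251 to 7918 ± 358 in version 3 (mean ± SD, n = 3 each). The log2 fold changes in input were -1.40 ± 0.07, -1.43 ± 0.08 and -1.67 ± 0.12 (limma, adjusted p = 4.18e-10, 3.67e-06 and 5.10e-05). In RIP they were -0.78 ± 0.07, -1.17 ± 0.08 and -1.61 ± 0.12 (limma, adjusted p = 2.91e-06, 4.72e-05 and 8.40e-05). With library weights the version 3 RIP value no longer passed (log2 fold change -1.65, adjusted p = 0.0624). ADARB1, which encodes the related editing enzyme ADAR2, did not pass in input (-0.02, -0.07 and -0.24), and ADARB2 was too low to test.

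**Figure D2:**
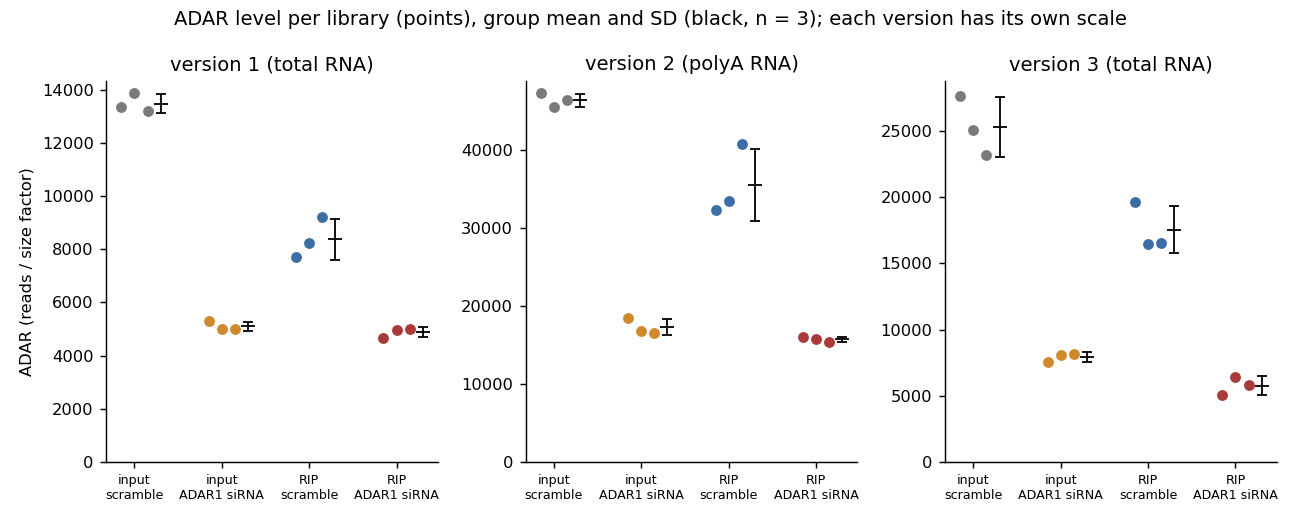
ADAR level in normalized reads in each library of the 4 groups of the 3 versions. Points are libraries, and bars show the group mean and SD (n = 3).

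In input RNA, knockdown raised interferon-induced genes in versions 1 and 2. IFIT2, whose product blocks translation of foreign RNA, rose by 1.26 ± 0.13 and 1.21 ± 0.12 log2 units (limma, adjusted p = 2.98e-05 and 0.000436). OASL, a cofactor of the RNA sensor RIG-I, rose by 1.12 ± 0.10 and 1.03 ± 0.10 (limma, adjusted p = 2.03e-06 and 0.000436). The chemokine genes CXCL10 (1.25 ± 0.17 and 1.20 ± 0.15) and CXCL11 (1.14 ± 0.16 and 1.09 ± 0.15), the death ligand gene TNFSF10 (1.17 ± 0.13 and 1.02 ± 0.11) and the zinc finger gene ZNF267 (1.49 ± 0.10 and 1.66 ± 0.17) rose in both. In version 3 none of these passed: IFIT2 stood at 0.30 ± 0.25, OASL at 0.35 ± 0.37, CXCL10 at 0.83 ± 0.37 and ZNF267 at 0.16 ± 0.26. Only 3 features passed in version 3 input, against 52 with only the compared groups in the model and 244 with library weights. The scarcity of calls there thus depended on the model, and a missing call does not show an absent change.

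The largest rise in both versions 1 and 2 was that of SLC25A47, a mitochondrial carrier gene mostly expressed in liver, by 2.98 ± 0.31 and 5.32 ± 0.84 (limma, adjusted p = 1.98e-05 and 0.0122). Its level in version 2 input went from 9.02 ± 3.84 to 381 ± 79.8 normalized reads. The version 2 call was lost in 5 of 12 leave-one-out runs, without input scramble 1, input scramble 3 or any 1 of input knockdown 1, 2 and 3 (highest adjusted p = 0.145). BATF2, an interferon-induced transcription factor gene, rose by 1.20 ± 0.10 and 1.16 ± 0.17 (limma, adjusted p = 6.84e-07 and 0.00734), and its version 2 call was lost without input scramble 1, input scramble 3 or input knockdown 3 (highest adjusted p = 0.0574). TMBIM6, which encodes an inhibitor of cell death in the endoplasmic reticulum, fell in all 3 versions (-0.75 ± 0.09, -0.83 ± 0.08 and -0.88 ± 0.12). Its version 3 call (limma, adjusted p = 0.0414) was lost without any 1 library other than RIP knockdown 3 (highest adjusted p = 0.381), with equal library totals, with no filter, with the replicate block and without the 3 shallow RIP libraries. The collagen gene COL1A1 fell by 0.77 ± 0.08 and 0.71 ± 0.08 (limma, adjusted p = 1.34e-05 and 0.00263), and LRRC17 and the cytoskeletal regulator gene DPYSL3 fell in both as well, while in version 3 COL1A1 stood at -0.05 ± 0.15 and LRRC17 at 0.32 ± 0.26.

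IL6ST, the gene of the shared receptor subunit of the interleukin 6 family, was the only gene to rise in version 3 input (1.15 ± 0.16, limma adjusted p = 0.0414). In versions 1 and 2 IL6ST stood at -0.14 ± 0.09 and -0.15 ± 0.19. Its version 3 call was lost in 10 of 12 leave-one-out runs (highest adjusted p = 0.381), with equal library totals (adjusted p = 0.215), with no filter, with the replicate block and without the 3 shallow RIP libraries.

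Among interferon-stimulated genes in input, 31 of 50 rose in version 1, 15 in version 2 and none in version 3, and none fell (list medians 0.39, 0.35 and 0.19). Adjusted over the list alone, 42, 38 and 0 rose. The list moved up in all 3 versions (limma camera, adjusted p = 4.07e-41, 2.24e-62 and 2.51e-15), and the shift passed with an estimated correlation too (0.0180, 0.00135 and 0.0321). Of genes for dsRNA sensing and signalling, 7 of 26 rose in version 1 and 5 in version 2, and adjusted over the list alone 12 rose and 2 fell in version 1 and 8 rose in version 2. DDX58, which encodes RIG-I, rose by 0.73 ± 0.08 in version 1, and IFIH1, which encodes the long dsRNA sensor MDA5, by 0.56 ± 0.09 (limma, adjusted p = 1.98e-05 and 0.000723). EIF2AK2, which encodes the dsRNA-activated kinase PKR, did not pass (0.16 ± 0.10). This list too moved up in all 3 (limma camera, adjusted p = 0.0180, 0.00186 and 0.0119 with an estimated correlation). Of interferons and inflammatory mediators, 11 of 27 rose in version 1 and 5 of 29 in version 2 (17 and 15 adjusted over the list alone), among them TNFAIP3, a brake on NF-kB signalling, by 0.63 ± 0.08 and 0.68 ± 0.09. The list shift passed with an estimated correlation (limma camera, adjusted p = 0.0492, 0.0103 and 0.0351).

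Fibroblast and mural markers moved the other way, with 7 of 12 fallen in version 1 and 3 in version 2 (8 and 7 adjusted over the list alone; medians -0.43 and -0.34), among them PDGFRB in version 1 (-0.57 ± 0.12), whose call was lost without input scramble 3 or input knockdown 2 (highest adjusted p = 0.0760). With an estimated correlation the shift passed at adjusted p = 0.0116 and 0.00281 (limma camera). Of astrocyte markers 1 of 14 fell in version 1 and 0 of 18 in version 2 (1 and 7 adjusted over the list alone), with a list shift of adjusted p = 0.0205 and 0.00423 with an estimated correlation (limma camera). Neither list moved in version 3 (limma camera, adjusted p = 0.390 and 0.712). Of the zinc finger genes 31 of 490 rose in version 1 and 2 of 499 in version 2 (list shift adjusted p = 0.0205 and 0.00423 with an estimated correlation, limma camera).

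Of integrated stress response genes 4 of 30 rose in version 1, among them ASNS, which makes asparagine (0.43 ± 0.09), and DDIT4 (0.40 ± 0.08), and none in version 2. The ASNS call was lost without input scramble 1 or input knockdown 3 (highest adjusted p = 0.0795). The list shift was lost in both with an estimated correlation (limma camera, adjusted p = 0.325 and 0.119). Cell cycle genes had 3 fallen of 30 in version 1 and none in version 2, and with an estimated correlation their shift passed in version 2 only (limma camera, adjusted p = 0.0215, against 0.228 in version 1). The version 1 call of the topoisomerase gene TOP2A (-0.56 ± 0.14) was lost in 5 of 12 leave-one-out runs (highest adjusted p = 0.160).

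Reactive astrocyte genes had 3 rising and 1 falling of 18 in version 1 and 1 falling in version 2, and p53 and apoptosis genes had 1 falling of 20 in version 1. Transcripts with inverted Alu copies had 1 rising of 15 (APOL1, 0.45 ± 0.10, lost in 3 of 12 leave-one-out runs), and recoding or intronic ADAR editing targets had 1 falling of 11, both in version 1 only. No member of the ribosomal protein or histone lists passed in input in any version. Neuron markers had 1 rising and 1 falling of 9, oligodendrocyte lineage markers 1 falling of 10, and endothelial markers none of 7 in version 1, and 1 oligodendrocyte lineage marker, CNP, rose in version 2 (0.34 ± 0.06, a call lost in 6 of 12 leave-one-out runs). Nuclear long noncoding RNAs had 1 falling of 10, snoRNA and scaRNA genes 3 falling of 306, and structured small noncoding RNAs 2 falling of 18 in version 1.

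**Figure D3:**
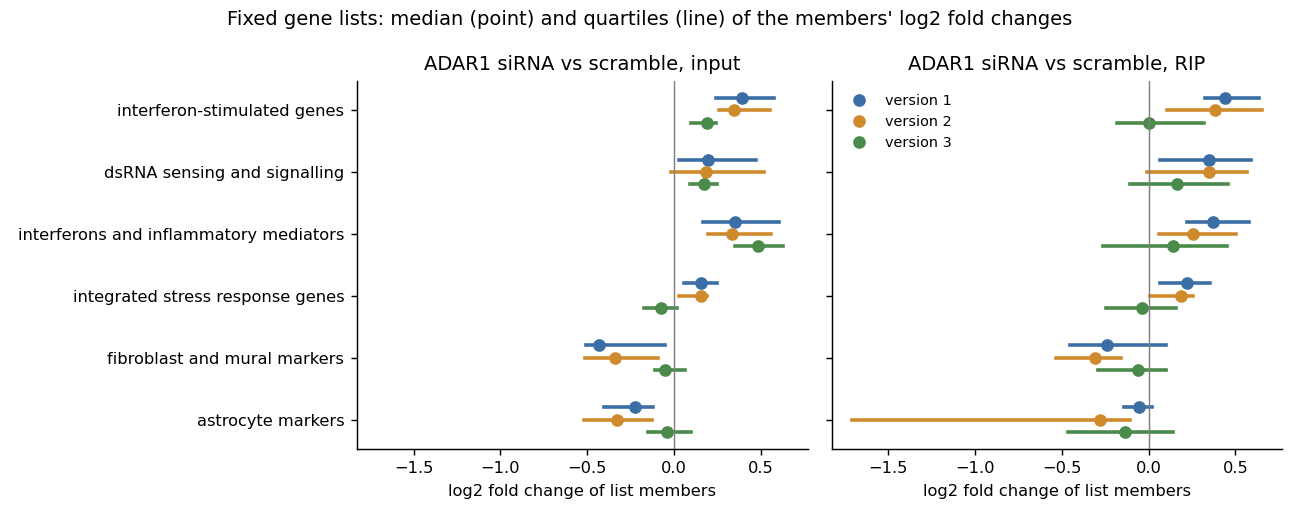
Log2 fold change of knockdown against scramble for 6 gene lists in input and in RIP of the 3 versions, as median and quartiles over list members. In version 3 the medians of dsRNA sensing, inflammatory and interferon-stimulated genes in RIP, and of fibroblast and astrocyte markers in input, lie near 0 and change sign under another scaling.

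In input, 792 of 18720 features passed in version 1 (469 rose, 323 fell), 122 of 19377 in version 2 (83 rose, 39 fell) and 3 of 18884 in version 3 (1 rose, 2 fell; limma, adjusted p below 0.05). Unadjusted p was under 0.05 for 3022, 1065 and 173 features. By edgeR the counts were 1186, 130 and 5, and by DESeq2 1333, 361 and 28. With equal library totals 40 rose and 6 fell in version 2, and 0 rose and 1 fell in version 3. The 792 of version 1 became 283 without input scramble 1, 312 without input scramble 3, 302 without input knockdown 2 and 251 without input knockdown 3. The 122 of version 2 became 19, 43 and 24 without input scramble 1, 2 and 3, 44, 24 and 19 without input knockdown 1, 2 and 3, 81 without RIP knockdown 2 and 277 without RIP scramble 3. The 3 of version 3 became 1 without any 1 of RIP scramble 1 and 2, RIP knockdown 1 and 2, input scramble 1, 2 and 3, and input knockdown 1 and 3.

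In J2-bound RNA, knockdown raised 9 features and lowered 4 alike in 3 versions, with a spread per feature shared with the input libraries. TRIM14, an adaptor of RNA sensing at mitochondria, rose by 0.60 ± 0.07, 0.63 ± 0.09 and 0.91 ± 0.13 (limma, adjusted p = 4.81e-05, 0.00281 and 0.00656). ZNF618 rose by 0.57 ± 0.07, 1.02 ± 0.13 and 1.10 ± 0.20 (limma, adjusted p = 8.26e-05, 0.00130 and 0.0144). BATF2 rose by 1.27 ± 0.10, 1.26 ± 0.17 and 1.28 ± 0.27 (limma, adjusted p = 7.81e-07, 0.00170 and 0.0290), and its version 3 call was lost without input scramble 2 or any 1 of input knockdown 1, 2 and 3 (highest adjusted p = 0.0654). That call was also lost with the replicate block (limma, adjusted p = 0.0518). DSP, the gene of desmoplakin, rose by 0.51 ± 0.13, 0.71 ± 0.12 and 1.27 ± 0.22, and its version 1 call was lost without RIP scramble 1, RIP scramble 2, RIP knockdown 2 or RIP knockdown 3 (highest adjusted p = 0.131). The version 3 calls did not hold with library weights (limma, adjusted p = 0.396 for TRIM14, 0.381 for ZNF618, 0.482 for BATF2 and 0.398 for DSP) or with only the compared groups in the model (0.204, 0.247, 0.455 and 0.378). ADAR, TMBIM6 (-0.55 ± 0.09, -0.68 ± 0.08 and -0.79 ± 0.12), the cyclin gene CCNG1 (-0.44 ± 0.12, -0.63 ± 0.14 and -1.32 ± 0.17) and the Polycomb gene CBX6 (-0.40 ± 0.10, -0.66 ± 0.09 and -0.68 ± 0.12) fell in all 3. In version 3 the calls of TMBIM6, CCNG1 and CBX6 were lost with library weights as well (limma, adjusted p = 0.428, 0.259 and 0.497), and those of TMBIM6 and CBX6 with only the compared groups (0.172 and 0.416). The 13 features alike became 0 with library weights and 1 with only the compared groups.

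The other risers alike in 3 versions were CNP, PML, which encodes the scaffold of an interferon-induced nuclear body, ASNS, GTPBP1 and CNST. Their version 3 calls were weaker: each was lost in 8 to 10 of 12 leave-one-out runs, and with equal library totals all 5 were lost (adjusted p = 0.247 for CNP, 0.174 for PML, 0.220 for ASNS, 0.103 for GTPBP1 and 0.131 for CNST). The version 1 call of CNST was lost in 6 of 12 runs as well (highest adjusted p = 0.135). The calls of CCNG1 were lost in version 1 without RIP scramble 1, RIP scramble 3 or RIP knockdown 3 (highest adjusted p = 0.0858) and in version 2 without RIP knockdown 2 or 3 (0.0654), and that of CBX6 in version 1 without RIP scramble 2 (0.0506). With only the compared groups in the model, the version 2 calls of TRIM14, DSP, CCNG1 and CBX6 were lost as well (limma, adjusted p = 0.0995, 0.181, 0.204 and 0.0789), as was the version 1 call of CCNG1 (0.103). Under that model PML, ASNS, GTPBP1 and CNST were lost in version 2 too (0.0839, 0.157, 0.226 and 0.319), and CNST in version 1 (0.155). With library weights CCNG1, PML, ASNS and CNST were lost in version 2 (0.0887, 0.0505, 0.182 and 0.126), and CNST in version 1 (0.0796).

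**Figure D4:**
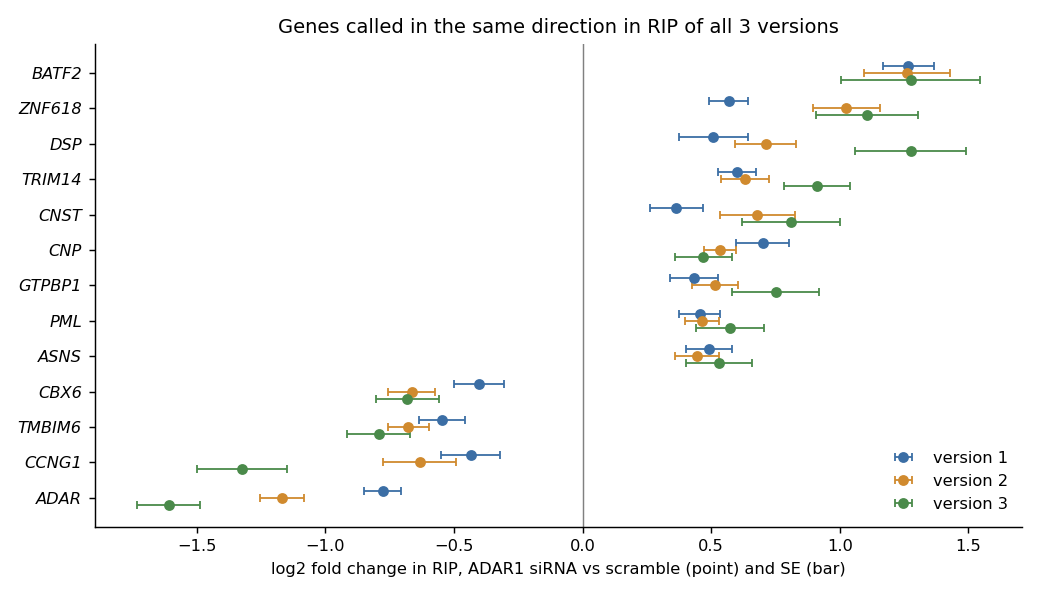
Log2 fold change of knockdown against scramble in RIP for the 13 genes alike in 3 versions, with standard errors (limma, n = 3 libraries per group).

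The interferon response of versions 1 and 2 was present in J2-bound RNA as well. IFIT2 rose by 1.39 ± 0.13 and 1.29 ± 0.12, OASL by 1.16 ± 0.10 and 1.12 ± 0.10, and RSAD2, which encodes the antiviral enzyme viperin, by 0.77 ± 0.09 and 0.76 ± 0.09 (limma, adjusted p = 7.04e-06 and 0.000110, 2.20e-06 and 0.000110, and 1.45e-05 and 0.000970). SLC25A47 rose by 2.93 ± 0.31 in version 1 and at least 79.3-fold in version 2, where no RIP scramble library held a read of it (0 against 254 ± 224 normalized reads), a version 2 call lost with only the compared groups (limma, adjusted p = 0.0910). IFIH1 rose by 0.68 ± 0.09 and 0.73 ± 0.12 and stood at -0.60 ± 0.24 in version 3, where it did not pass (limma, adjusted p = 0.179), and its version 2 call was lost with only the compared groups (0.0570). ZNF267 rose by 1.11 ± 0.10 and 1.88 ± 0.17 and stood at -0.48 ± 0.26 in version 3 (limma, adjusted p = 0.306).

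Of 50 interferon-stimulated genes, 36 rose in version 1 and 28 in version 2, and in version 3 1 rose and 1 fell (medians 0.44, 0.38 and 0.00). Adjusted over the list alone 42, 31 and 6 rose and 3 fell in version 3. The list moved up in versions 1 and 2 with an estimated correlation (limma camera, adjusted p = 0.0454 and 0.0364) and not in version 3 with the preset one (0.490). Of genes for dsRNA sensing 14 of 26 rose in version 1, and 8 rose and 1 fell in version 2 (15 rising adjusted over the list alone in version 2; list shift adjusted p = 0.00961 and 0.0364 with an estimated correlation). Among them DDX58 rose by 0.70 ± 0.08 and 0.93 ± 0.12, and EIF2AK2 rose in version 1 (0.38 ± 0.10), a call lost without RIP scramble 1, RIP scramble 2 or RIP knockdown 2 (highest adjusted p = 0.0877) and with only the compared groups (0.0526). Of inflammatory mediators 14 of 27 rose in version 1 and 7 of 29 in version 2, with TNFAIP3 at 0.89 ± 0.08 and 0.87 ± 0.09, and the list shift was lost with an estimated correlation (limma camera, adjusted p = 0.102 and 0.259). Integrated stress response genes had 10 rising of 30 in version 1 and 4 rising and 1 falling in version 2 (15 rising in version 1 adjusted over the list alone; adjusted p = 0.218 and 0.370 with an estimated correlation).

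Of 15 transcripts known for inverted Alu copies, 5 rose in version 1 and 3 in version 2. They included APOL1 (0.53 ± 0.10 and 0.66 ± 0.10), DESI1 (0.48 ± 0.08 and 0.50 ± 0.10) and XIAP, an inhibitor of caspases (0.44 ± 0.07 and 0.47 ± 0.10), whose version 2 call was lost without RIP scramble 2 (adjusted p = 0.0583). With only the compared groups the version 2 calls of all 3 were lost (limma, adjusted p = 0.0789 for APOL1, 0.205 for DESI1 and 0.294 for XIAP), and with library weights those of DESI1 and XIAP (0.0902 and 0.0810). In version 3 none passed (DESI1 0.46 ± 0.14). The list shift in versions 1 and 2 was lost with an estimated correlation (limma camera, adjusted p = 0.326 and 0.414). Of recoding or intronic ADAR editing targets 1 rose in version 1, AZIN1, a known recoding target (0.43 ± 0.08, limma adjusted p = 0.00265).

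Nuclear long noncoding RNAs had 2 rising and 4 falling of 10 in J2-bound RNA of version 1 and 1 falling in version 3, and the list did not pass in any version (limma camera, adjusted p = 0.0901 in version 1). KCNQ1OT1 fell in version 1 (-0.35 ± 0.08) and version 3 (-1.60 ± 0.29), and NEAT1, the core RNA of paraspeckles, fell in version 1 (-0.42 ± 0.09). The version 1 call of KCNQ1OT1 was lost without RIP scramble 1 or RIP knockdown 2 (highest adjusted p = 0.0679), and its version 3 call with library weights (0.404) and with only the compared groups (0.158). Of fibroblast and mural markers 3 of 12 fell in each of versions 1 and 2 and 1 rose in version 1 (adjusted p = 0.122 and 0.0453 with an estimated correlation), and COL1A1 fell by 0.54 ± 0.08 in both. Of 84 ribosomal protein genes 2, 10 and 6 fell, and the shift was lost with an estimated correlation (limma camera, adjusted p = 0.568 and 0.320 in versions 1 and 2).

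Zinc finger genes had 40 rising and 4 falling of 490 in version 1, 33 and 4 in version 2, and 2 and 7 in version 3 (adjusted p = 0.0929 and 0.0453 with an estimated correlation in versions 1 and 2). Reactive astrocyte genes had 5 rising and 2 falling in version 1 and 4 and 3 in version 2, p53 and apoptosis genes 3, 1 and 1 rising, and cell cycle genes 1 and 3 falling in versions 1 and 2 and 2 rising in version 3. Astrocyte markers had 1 and 2 falling in versions 1 and 2, histone genes 6 falling in version 1, 2 rising in version 2 and 1 falling in version 3, and snoRNA and scaRNA genes 2 and 4 falling in versions 1 and 3. Endothelial markers had 1 falling and neuron markers 1 rising in version 1, oligodendrocyte lineage markers 1 rising in each version and 1 falling in version 3, and structured small noncoding RNAs none.

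With knockdown in J2-bound RNA, 161 repeat subfamilies fell and 2 rose in version 1, 11 fell and 3 rose in version 2, and 1 fell and 2 rose in version 3. Without the 3 shallow libraries, 13 of 132 L1, 33 of 295 ERV1, 27 of 123 ERVL and no Alu subfamilies rose in version 3, and 3 ERV1 subfamilies fell. That run had 1 RIP knockdown library, its lists were not tested, and it gives no direction for the repeat families. In version 1, 46 of 132 L1 subfamilies fell and none rose (median -0.23), and 9 fell with equal library totals; the list shift was lost with an estimated correlation (limma camera, adjusted p = 0.229). No Alu subfamily passed in any version, and AluSx1 stood at -0.01, 1.99 ± 0.67 and 0.20 ± 0.20 (limma, adjusted p = 0.127 in version 2).

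In RIP, 1564 features passed in version 1 (987 rose, 577 fell), 964 in version 2 (576 rose, 388 fell) and 443 in version 3 (169 rose, 274 fell). By edgeR the counts were 1235, 902 and 301, and by DESeq2 1646, 2227 and 1738. The 443 of version 3 became 1 with library weights, 2 with only the compared groups in the model and 3570 without the 3 shallow libraries. The version 3 RIP groups also differed in their share of ribosomal RNA, as given above, and its part in these calls was not tested. With equal library totals 347 rose and 435 fell in version 2, and 79 rose and 513 fell in version 3. The median of all features in version 3 then stood at -0.22. The 1564 of version 1 became 780 without RIP scramble 1, 2870 without RIP scramble 3, 886 without RIP knockdown 2 and 1033 without RIP knockdown 3.

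The 964 of version 2 in RIP became 3248 without RIP scramble 3, 630 and 633 without input scramble 1 and 3, and 636, 598 and 623 without input knockdown 1, 2 and 3. The 443 of version 3 became 904, 760 and 1289 without RIP knockdown 1, 2 and 3, 292, 183 and 264 without input scramble 1, 2 and 3, and 183, 190 and 166 without input knockdown 1, 2 and 3.

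In scramble cells, many ribosomal protein messengers were lower and many repeat subfamilies higher in J2-bound RNA than in input, though no shift of these lists passed with an estimated correlation. Without a control pull-down, binding by J2 and unspecific carry-over could not be told apart in RIP against input. RPLP1, a gene of the ribosomal stalk, fell by 2.79 ± 0.10, 2.85 ± 0.13 and 2.42 ± 0.20 log2 units (limma, adjusted p = 4.03e-14, 4.76e-08 and 5.54e-06). RPL12 fell by 3.04 ± 0.12, 2.50 ± 0.18 and 2.45 ± 0.25. L1HS, the youngest human L1 subfamily, rose by 1.62 ± 0.08, 1.33 ± 0.15 and 2.49 ± 0.28 (limma, adjusted p = 1.54e-12, 4.88e-05 and 4.75e-05), and the older L1PREC2 by 1.35 ± 0.08, 1.85 ± 0.22 and 1.41 ± 0.24, a version 1 call that was lost with equal library totals. The simple repeat (GAATG)n, the unit of human satellites 2 and 3, rose by 4.18 ± 0.97, 1.46 ± 0.33 and 4.59 ± 0.48. These directions hold relative to the rest of the library: with equal library totals the median of all features was -1.24, -0.24 and -0.41.

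Reads of ribosomal RNA rose in the 2 total RNA versions. The kits deplete ribosomal RNA, so reads that escaped depletion and binding by J2 could not be told apart. RNA18S5 rose by 13.15 ± 0.52 in version 1 and 5.33 ± 0.60 in version 3 (limma, adjusted p = 4.22e-08 and 6.08e-05), and RNA28S5 by 10.88 ± 0.44 and 5.65 ± 0.52, while in version 2 both stood at 0.37 and did not pass. RNA18S5 went from 373 ± 245 to 3030780 ± 736289 normalized reads in version 1. The short RNA5-8S5 rose in all 3 (7.12 ± 0.57, 2.03 ± 0.40 and 3.90 ± 0.97), and its version 3 call was lost without input scramble 1 (adjusted p = 0.0523). IFITM1, which encodes a small interferon-induced membrane protein, fell in all 3 (-3.09 ± 0.08, -1.94 ± 0.11 and -1.62 ± 0.23; limma, adjusted p = 1.50e-16, 3.12e-07 and 0.000212), as did IFI27. NEAT1 rose by 2.93 ± 0.09, 1.24 ± 0.25 and 0.60 ± 0.20, and KCNQ1OT1 by 1.77 ± 0.08 and 2.08 ± 0.26 in versions 1 and 2. The version 3 call of NEAT1 (limma, adjusted p = 0.0420) was lost in 8 of 12 leave-one-out runs (highest adjusted p = 0.194). It was also lost with no filter, equal library totals, only the compared groups, the replicate block, library weights and edgeR (highest adjusted p = 0.118, with equal library totals).

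In version 3, FOXA2, a transcription factor gene of endoderm, rose by 8.32 ± 0.48 (limma, adjusted p = 6.96e-07), from 17.2 ± 2.87 to 6829 ± 5067 normalized reads. COL1A1, unlike in version 2 (0.15 ± 0.08), fell by 2.32 ± 0.15 in version 3, and the filamin gene FLNA fell by 2.27 ± 0.16 there and stood at 0.00 ± 0.13 in version 1.

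Among repeat families, 51 of 51 Alu, 132 of 132 L1 and 293 of 297 ERV1 subfamilies rose in version 1, where 1 ERV1 subfamily fell. The Alu and ERV1 medians of 1.23 and 1.26 became 0.01 and 0.04 with equal library totals, and the L1 median became 0.09. In version 2, 49 of 51 Alu subfamilies (median 1.76), 116 of 129 L1 (1.37) and 97 of 296 ERV1 (0.68) rose, and 1 L1 and 4 ERV1 subfamilies fell. In version 3, 11 Alu (0.47), 111 L1 (1.07) and 97 of 295 ERV1 (0.91) rose, and 1 L1 subfamily fell. Satellite subfamilies rose in 11, 5 and 9 of 12 cases (medians 2.09, 0.62 and 1.52; 0.88 in version 1 with equal library totals). AluSx1 rose by 1.28 ± 0.11, 2.37 ± 0.67 and 1.19 ± 0.20, a call lost in version 1 with equal totals and in version 2 without any 1 of input scramble 1, 2 and 3 (highest adjusted p = 0.0789). The version 2 call was also lost with the replicate block (limma, adjusted p = 0.0547). With an estimated correlation no repeat family shift passed (limma camera, adjusted p = 0.0945, 0.180 and 0.313 for Alu and 0.0805, 0.180 and 0.216 for L1). Of ERVK, ERVL, ERVL-MaLR, hAT-Charlie, L2, MIR and TcMar-Tigger subfamilies 39, 124, 82, 74, 9, 5 and 63 rose in version 1. With equal library totals the medians of all of these but L2 were below 0 there.

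**Figure D5:**
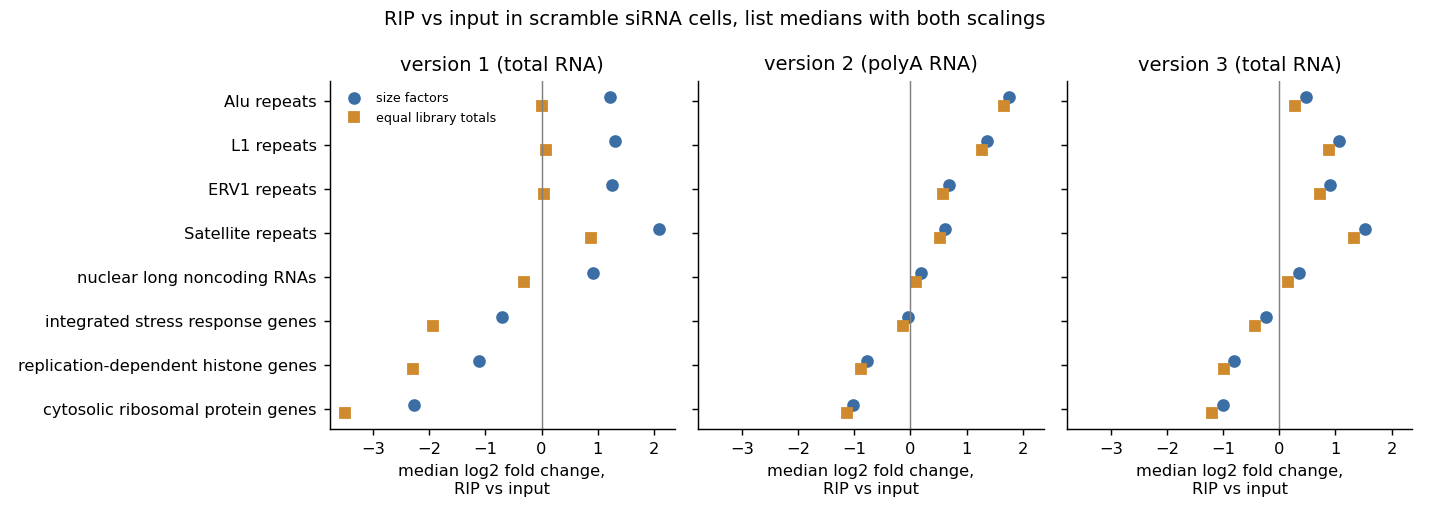
Median log2 fold change of RIP against input in scramble cells for 8 lists, with the deposited size factors and with equal library totals. The nuclear long noncoding RNA median in version 1 changes sign between the 2 scalings.

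Of 84 ribosomal protein genes, 82 fell in version 1, 58 fell and 13 rose in version 2, and 49 fell and 3 rose in version 3 (medians -2.28, -1.03 and -1.01; 82, 58 and 53 fell adjusted over the list alone). The list shift was lost with an estimated correlation (limma camera, adjusted p = 0.124, 0.636 and 0.195). Histone genes fell in 49 of 69, 10 of 49 and 2 of 67 cases and rose in 4, 1 and 0 (adjusted p = 0.119 with an estimated correlation in version 1). Interferon-stimulated genes had 5 rising and 36 falling in version 1, 16 and 18 in version 2, and 9 and 14 in version 3, with a list shift in version 1 only that was lost with an estimated correlation (limma camera, adjusted p = 0.294). Integrated stress response genes had 28 of 30 falling in version 1 (0.170 with an estimated correlation), 5 rising and 11 falling in version 2, and 8 and 11 in version 3. Inflammatory mediators had 2 rising and 24 falling of 27 in version 1, 4 and 9 in version 2, and 7 and 2 in version 3 (versions 1 and 3 at 0.250 and 0.625 with an estimated correlation). Fibroblast and mural markers fell in 9 of 12 cases in version 3 (0.0942 with an estimated correlation).

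The snoRNA and scaRNA genes rose in 251 of 306 cases in version 1 and fell in 3 (median 1.69, and 0.57 with equal library totals), with SNORA73B at 5.63 ± 0.10, while 8 of 162 rose and 10 fell in version 2 and 4 of 220 rose and 9 fell in version 3. The signal recognition particle RNA gene RN7SL2 rose by 4.79 ± 0.13 in version 1 and fell by 2.92 ± 0.55 in version 3 (limma, adjusted p = 3.04e-14 and 0.00204). Of 18 structured small noncoding RNAs 11 rose and 2 fell in version 1 (median 0.97, and -0.21 with equal library totals), and 4 of 13 fell in version 3. Nuclear long noncoding RNAs rose in 7, 4 and 3 of 10 cases and fell in 3, 3 and 0, with a version 1 median of 0.91 that became -0.31 with equal library totals. These shifts were lost with an estimated correlation (limma camera, adjusted p = 0.119 for snoRNA, 0.294 for structured small and 0.137 for nuclear long noncoding RNAs in version 1).

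Transcripts with inverted Alu copies had 2 rising and 9 falling of 15 in version 1, 3 and 1 in version 2, and 5 and 1 in version 3, where the list shift was lost with an estimated correlation (limma camera, adjusted p = 0.195). NICN1 rose by 1.08 ± 0.10 in version 1 and stood at -0.13 there with equal library totals. Genes for dsRNA sensing had 6 and 11, 6 and 4, and 3 and 9 rising and falling in the 3 versions, and editing targets 1 and 7, 2 and 5, and 1 and 4. Zinc finger genes had 116 rising and 120 falling in version 1, 44 and 72 in version 2, and 72 and 40 in version 3. In version 1 astrocyte markers had 0 rising and 7 falling of 14, cell cycle genes 1 and 11 of 30, p53 and apoptosis genes 2 and 13 of 20, reactive astrocyte genes 3 and 11 of 18, and neuron markers 1 and 6 of 9. Oligodendrocyte lineage markers had 5 rising and 3 falling there, and endothelial markers 1 and 1. In version 3 p53 and apoptosis genes had 7 rising and 5 falling, and in version 2 reactive astrocyte genes had 8 and 4.

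In scramble cells 12240 features passed in version 1 (5824 rose, 6416 fell), 6088 in version 2 (2769 rose, 3319 fell) and 4747 in version 3 (2159 rose, 2588 fell; limma). Of the risers 1141, 499 and 509 were repeat subfamilies, and of the fallers 1, 15 and 2. With equal library totals 782 rose and 13937 fell in version 1, and 1324 rose and 3316 fell in version 3. The version 3 count became 2748 without input scramble 1, and no other left-out library moved a count of this comparison by more than 1.5 times.

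Without the 3 shallow RIP libraries, version 3 counts of list members moved in many cases, with 2 RIP scramble libraries and 1 RIP knockdown library left, and no list shift was tested there. In scramble cells, snoRNA and scaRNA genes in RIP against input then had 41 rising and 23 falling of 220, histone genes 0 and 21, zinc finger genes 149 and 79, and Alu, L1, ERV1 and ERVL subfamilies 36, 125, 206 and 93 rising. Interferon-stimulated genes had 8 rising and 16 falling there, inflammatory mediators 11 and 4, cell cycle genes 0 and 11 and astrocyte markers 1 and 8. In knockdown cells Alu, L1 and ERV1 subfamilies had 45, 131 and 250 rising and histone genes 28 falling. For knockdown in RIP, interferon-stimulated genes had 6 rising and 1 falling, zinc finger genes 34 and 71, snoRNA and scaRNA genes 14 and 43, histone genes 1 and 13 and ribosomal protein genes 0 and 12.

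In knockdown cells the J2-bound RNA differed from input along the same lines. The satellite GSATII rose by 2.58 ± 0.18, 2.16 ± 0.34 and 2.45 ± 0.50 (limma, adjusted p = 5.09e-10, 0.000548 and 0.00352). The young subfamily AluYa5 rose by 1.60 ± 0.18, 4.09 ± 0.46 and 1.33 ± 0.30 (limma, adjusted p = 6.28e-06, 4.21e-05 and 0.00625), AluSx1 by 1.29 ± 0.11, 4.36 ± 0.67 and 1.63 ± 0.20, and L1HS by 1.34 ± 0.08, 1.03 ± 0.15 and 3.90 ± 0.28. The version 1 calls of AluSx1 and L1HS were lost with equal library totals. RPL39 fell by 3.84 ± 0.19, 2.96 ± 0.20 and 3.09 ± 0.33, RPS21 by 2.74 ± 0.16, 2.56 ± 0.21 and 3.16 ± 0.36, and IFITM1 stood at -3.17 ± 0.08, -2.21 ± 0.11 and -1.85 ± 0.23. FOXA2 rose by 9.47 ± 0.48 in version 3 (limma, adjusted p = 3.45e-07).

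Ribosomal protein genes fell in 82, 60 and 50 of 84 cases and rose in 0, 6 and 5, and histone genes fell in 52 of 69, 11 of 49 and 12 of 67. Alu subfamilies rose in 49, 49 and 33 of 51 cases and L1 subfamilies in 132 of 132, 101 of 129 and 117 of 132, where 0, 2 and 1 fell. In version 1 the Alu and L1 medians of 1.10 and 1.04 became -0.11 and -0.17 with equal library totals. Satellite subfamilies rose in 9, 4 and 11 of 12 cases. Interferon-stimulated genes had 7 rising and 35 falling in version 1, 14 and 16 in version 2, and 2 and 13 in version 3, and integrated stress response genes 2 and 26, 9 and 9, and 8 and 8. Transcripts with inverted Alu copies had 3 rising and 8 falling in version 1, 7 and 2 in version 2, and 5 and 0 in version 3, with a version 3 median of 0.35 that became -0.09 with equal library totals. No list shift passed with an estimated correlation (limma camera, adjusted p = 0.151, 0.449 and 0.229 for ribosomal protein genes, 0.0996, 0.368 and 0.156 for Alu, and 0.367 for interferon-stimulated genes in version 1).

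In knockdown cells 11606 features passed in version 1 (5577 rose, 6029 fell), 5102 in version 2 (2348 rose, 2754 fell) and 4089 in version 3 (1730 rose, 2359 fell; limma). With equal library totals 665 rose and 14583 fell in version 1, 1496 and 3609 in version 2, and 733 and 4943 in version 3. The version 2 count became 3305, 3325 and 3240 without input knockdown 1, 2 and 3, and the version 3 count 2533, 2245 and 2345.

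For the interaction, whether J2 enrichment itself changed with knockdown, no feature passed in any version by limma, with unadjusted p under 0.05 for 1922, 1194 and 1451 features. The count was 0 in each by edgeR, 15, 100 and 137 by DESeq2, and 104 in version 1 with library weights, so the absence of calls depended on the method. The run of version 3 without its 3 shallow libraries leaves 1 RIP knockdown library and cannot decide this. ADAR stood at 0.63 ± 0.10, 0.26 ± 0.12 and 0.06 ± 0.18 and did not pass (limma, adjusted p = 0.0996, 0.784 and 0.934). XIAP stood at 0.36 ± 0.11 and 0.34 ± 0.15 in versions 1 and 2 (limma, adjusted p = 0.438 and 0.784), L1HS at -0.28 ± 0.11, -0.30 ± 0.22 and 1.41 ± 0.40 (0.438 in version 1 and 0.444 in version 3), and MAVS, the adaptor of RNA sensors, at 0.59 ± 0.20 in version 3 (0.554). BATF2, IFIT2, SLC25A47 and AluSx1, chosen after their values were seen, did not pass either (AluSx1 2.00 ± 0.95 in version 2, limma adjusted p = 0.784).

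Interferon-stimulated genes did not shift in the interaction (limma camera, adjusted p = 0.345, 0.947 and 0.370). Ribosomal protein genes shifted down in versions 1 and 2 (medians -0.17 and -0.26), and transcripts with inverted Alu copies shifted up (0.08 in both). Both shifts were lost with an estimated correlation (limma camera, adjusted p = 0.708 and 0.951, and 0.544 and 0.951), as were all others. No interaction count without a library was above 0 in version 1 except 43 without RIP scramble 3. In version 2 the counts were 2, 2 and 178 without RIP scramble 1, 2 and 3, and in version 3 5, 20 and 138 without RIP knockdown 1, 2 and 3. In simulation the test recovered 4% to 69.7% of genes with a 2-fold interaction, so absent calls do not exclude changes of that size.

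Across versions, ADAR and TMBIM6 passed alike in input, of 17309 features tested in all 3, where 0.000212 were expected for independent lists. With only the compared groups 11 rose and 5 fell alike in input, and with library weights 40 rose and 26 fell. In RIP 13 passed alike (0.466 expected), in RIP against input 803 in scramble cells (356 up, 447 down; 260 expected) and 670 in knockdown cells (312 up, 358 down; 178 expected). Repeats made up 334 of the 356 and 299 of the 312. Under equal library totals 917 were alike in scramble cells (30 up, 887 down) and 1332 in knockdown cells (5 up, 1327 down), so the near-even split and the many repeats among the risers depend on the scaling. Versions 1 and 2 shared 75 rising and 36 falling features in input (2.22 and 0.723 expected) with none opposite, and 318 rising and 73 falling in RIP (31.4 and 11.7 expected) with 2 opposite (38.4 expected). Knockdown effects in input correlated across genes at r = 0.53 between versions 1 and 2, 0.14 between 1 and 3, and 0.15 between 2 and 3. Genes are not independent replicates, and differences between versions were not tested.

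For RIP against input in scramble cells, versions 1 and 3 shared 585 rising and 1053 falling features (596 and 917 expected), and 1774 passed in opposite directions (1481 expected). Versions 1 and 2 shared 1437 and 2202 (772 and 1149 expected), with 832 opposite (1888 expected). Versions 2 and 3 shared 523 and 633 (336 and 450 expected), with 1052 opposite (778 expected). In knockdown cells versions 1 and 3 shared 743 rising and 730 falling features (464 and 762 expected), with 1301 opposite (1190 expected). Versions 1 and 2 shared 1081 and 1748 there (646 and 901 expected), with 815 opposite (1528 expected). Versions 2 and 3 shared 471 and 577 (226 and 333 expected), with 507 opposite (551 expected). Input and RIP effects of knockdown shared 319 rising and 85 falling features in version 1 (24.7 and 9.96 expected), 77 and 29 in version 2 (2.47 and 0.781), and 1 and 2 in version 3, with none opposite.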

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

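The tests of library scaling, of length and of Alu pairing within each version, of weaker knockdown and of ribosomal RNA placement were chosen only after the results were seen. The tests of chance splits, of pooled length, of spread between libraries, of epithelial RNA and of genomic DNA were written before their results were seen.

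Repeat subfamilies stood higher in RIP than in input of scramble cells, and 3 explanations were weighed. Library scaling did not account for it in versions 2 and 3, where 79.3% and 89.0% of repeat subfamilies lay above 0 with equal library totals. In version 1 50.8% did. Ribosomal RNA took 41.5% of version 1 RIP reads and lowers all else at equal totals, so this share cannot decide there. Version 1 repeats stood above genes under both scalings (medians 1.22 and -0.0985 with size factors, 0.00401 and -1.30 with equal totals). Another scaling shifts all features of a library by nearly the same amount. The distance between repeats and genes could therefore hardly change, and it is no test of scaling. A gain of long or unspliced transcripts was tested by rank correlation with genomic span across genes, which are not independent replicates. The pooled test, written before, came out against such a gain across genes in all 3 versions, with a lowest rho of -0.109 (versions 1 and 2 at -0.0506 and -0.109). Version 3 stood at 0.227. The test used genes and not repeats, and whether reads in introns were counted for genes is not given. It therefore cannot decide whether unspliced transcripts gave the repeat reads, which stays open until tested on other data. Pairing of inverted Alu copies was predicted to put Alu above other repeats, and the difference of medians was 0.00951, 1.04 and -0.401 in the 3 versions. Alu thus lay above other repeats in version 2 only, and below them in version 3, where its median was 0.471. Subfamily totals hold neither position nor orientation of the copies, so this test cannot decide on pairing in any version.

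Interferon-stimulated genes passed in input of versions 1 and 2 and not of version 3. A weaker knockdown did not account for it, since ADAR stood at -1.67 in version 3 input, the largest loss of the 3 versions. Wider spread in version 3 could explain part of it: for 64.5% of the 31 genes called in version 1 the version 3 interval reached the version 1 value. The median SE of all 50 genes was 0.0873, 0.0997 and 0.176 in the 3 versions. The median of the 31 was also lower in version 3 (0.54, 0.51 and 0.21 in the 3 versions; 29 of 31 above 0), so spread alone is left open. The difference between versions was not tested.

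KLHL40, FOXA2, MRGPRE and PDX1 were high in version 3 RIP, with KLHL40, MRGPRE and PDX1 near absent from input and FOXA2 low there (17.2 ± 2.87 normalized reads), and 3 explanations were weighed. For placement of ribosomal RNA reads on them, no version 1 RIP library, with far more ribosomal RNA, held more than 16 reads of any of the 4. The most abundant feature was RNA28S5 in version 1 RIP libraries and RNA45S5 in those of version 3. Which depletion each version used is not given either, so this test cannot exclude placement in version 3. RNA of epithelial or endoderm cells did not account for it, with a median of -1.88 for the marker list in version 3 RIP against input. Carried genomic DNA would raise most silent genes, and only 0.120% of 8300 low input features (10) were over 100 normalized reads in RIP scramble. The cause remains open.

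With 3 libraries against 3 there are only 10 splits, too few for a share under 0.05. For knockdown in input, the real split called 792, 122 and 3 features and the highest other split 0 in each version. For RIP against input the real counts were 12240, 6088 and 4747 in scramble cells and 11606, 5102 and 4089 in knockdown cells, and the highest other was 0. For knockdown in RIP the real and highest other counts were 1564 and 18 in version 1, 964 and 1235 in version 2, and 443 and 365 in version 3. In versions 2 and 3 the high split set RIP scramble 1 and 2 with RIP knockdown 3 as 1 group, so these RIP libraries differed by something other than the siRNA. In version 3 the other side of that split was the 3 shallowest libraries (RIP scramble 3 with 9.21 M reads, RIP knockdown 1 with 10.4 M and RIP knockdown 2 with 8.76 M). The split thus followed depth there, and effects of depth and siRNA could not be told apart fully. In version 2 the same split did not follow depth. RIP scramble 1 and 2 and RIP knockdown 3 held 44.6, 39.9 and 37.8 M reads there. RIP scramble 3 and RIP knockdown 1 and 2 held 42.5, 38.8 and 41.6 M. Depth therefore does not account for the split in version 2, and what set these libraries apart was not tested. Counts as large as the real split occurred in 2 of 10 splits in version 2 and in 1 of 10 in the other cases. For the interaction the real count of 0 was reached in 100 of 100 splits and the highest other was 2379, 936 and 37, given by exchanging the input labels, which adds both knockdown effects by construction.

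The next values were sought among the named genes only. They were marked because all 3 libraries of each group stood apart in opposite directions in different versions. By chance 10% of features would stand apart in 1 version, and the difference between versions was not tested. Opposite calls were common in RIP against input, with 2687 of 17309 features in scramble cells and 2047 in knockdown cells. The genes marked there are therefore not unusual. For knockdown, 19 features had opposite calls in RIP and 0 in input. In input after knockdown IL6ST stood at -0.14 in version 1 and 1.15 in version 3. In RIP after knockdown IFIH1 stood at 0.68, 0.73 and -0.60, ZNF267 at 1.11, 1.88 and -0.48, and ALDH1L2 at 0.41 in version 1 and -0.61 in version 3.

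For RIP against input in scramble cells FOXA2 was at least 3.60-fold lower in version 2, a call lost in 9 of 12 leave-one-out runs (highest adjusted p = 0.137), and stood at 8.32 in version 3. The signal recognition particle RNA RN7SL2 stood at 4.79 in version 1 and -2.92 in version 3, and RMRP, the RNA of an endoribonuclease, at 1.70 and -2.13. STAU1, a dsRNA-binding protein gene, stood at -1.19 in version 1 and 0.42 in version 3, ADARB1 at 0.29 and -0.61, where it did not pass (limma, adjusted p = 0.184), and ATF4 at -1.19 in version 1 and 0.30 in version 2. The version 3 call of STAU1 was lost in 7 of 12 leave-one-out runs (highest adjusted p = 0.0882) and the version 2 call of ATF4 in 3 (0.113). Over the 3 versions PSMB2 stood at -0.95, 0.24 and 0.38, PAICS at -0.69, 0.19 and 1.15, and CCNI at -1.18, -0.53 and 0.97.

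For RIP against input in knockdown cells the values over the 3 versions were -0.85, 0.33 and -0.45 for OAS1, -1.32, 0.17 and -0.48 for ATF4, -0.35, 0.82 and 0.79 for APOL1, 1.34, -0.77 and 1.61 for L1PA12, and -0.97, -0.24 and 1.15 for CCNI. The version 3 call of ATF4 was lost without input knockdown 2 or 3 (highest adjusted p = 0.0691) and the version 2 call of OAS1 without input knockdown 1 (0.0521). SNORA73B stood at 5.44 in version 1, was at least 4.69-fold lower in version 2, a call lost in 9 of 12 leave-one-out runs (highest adjusted p = 0.191), and stood at 2.42 in version 3, lost in 5 of 12 (0.0921). PSMB2 stood at -0.87 in version 1 and 0.28 in version 2, a version 2 call lost in 8 of 12 (0.157), and SNORA16A at 4.79 and -2.79. RN7SL2 stood at 5.42 in version 1 and -3.27 in version 3, and RMRP at 1.36 and -1.04. Marking did not require a pass, and these did not pass: IL6ST in version 1 and IFIH1, ZNF267 and ALDH1L2 in version 3 after knockdown, PSMB2 in versions 2 and 3 and PAICS in version 2 in scramble cells, and OAS1, APOL1 and RMRP in version 3 and ATF4, CCNI and SNORA16A in version 2 in knockdown cells. Under equal library totals the version 1 value of ADARB1 turned to -0.93, the same side as version 3, so its opposite directions depend on the scaling. The calls of STAU1 in version 3 and ATF4 in version 2 (scramble cells), and of OAS1 and PSMB2 in version 2 and L1PA12 and RMRP in version 1 (knockdown cells), were lost under equal library totals as well (limma, adjusted p = 0.339, 0.177, 0.263, 0.425, 0.158 and 0.184). With library weights the version 3 call of ATF4 and the version 2 call of PSMB2 in knockdown cells, and the version 2 call of FOXA2 in scramble cells, were lost (0.219, 0.116 and 0.0833). That FOXA2 call was also lost with a pseudocount of 4 (limma, adjusted p = 0.0823), only the compared groups, the replicate block, edgeR and DESeq2. The version 2 call of SNORA73B in knockdown cells was lost with a pseudocount of 4 (limma, adjusted p = 0.0918), only the compared groups and the replicate block.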

How the results depend on the processing

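The cause of each change below was not tested. With only the compared groups in the model, knockdown comparisons did not share their spread between input and RIP. Their counts then rose in input and fell in RIP in all 3 versions. ADAR kept its direction in every setting and passed in all but 1: with library weights it stood at -1.65 in version 3 RIP (adjusted p = 0.0624). Of 766 named-gene values, which cover every candidate of the naming rule and more than the text prints, 476 passed. Of these 474 kept the call with a pseudocount of 4, 458 with edgeR, 427 with library weights, 425 with equal library totals and 404 with only the compared groups. DESeq2 gave a value for 463 of them and kept 460, and gave 31 other calls. Library weights gave 46 other calls, and only the compared groups gave 35. With equal library totals 6 called values of version 1 turned: NICN1 -0.13, MDM4 -0.67 and ADARB1 -0.93 for RIP against input in scramble cells, and NICN1 -0.0493, MDM4 -0.63 and MALAT1 -0.47 in knockdown cells. FLNA, not called at 0.00 in version 1 scramble cells, passed at -1.22. Of 465 list results 220 passed, and 23 of these kept the call with an estimated correlation and 133 with fry, which gave 47 others.

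For knockdown in input, counts in version 1 (792) were 1333 with DESeq2, 5330 with library weights and 2063 with only the compared groups. In version 2 (122) they were 361, 2818 and 2512, and 46 with equal library totals. In version 3 (3) they were 28, 244 and 52, 5 with edgeR, and 1 with equal library totals, with no filter and without the 3 shallow RIP libraries. For knockdown in RIP, version 1 (1564) gave 501 with only the compared groups. Version 2 (964) gave 2227 with DESeq2, 301 with library weights and 41 with only the compared groups, and version 3 (443) 1738, 1 and 2, and 3570 without the shallow libraries. Without them version 3 gave 8651 and 7715 for RIP against input in scramble and knockdown cells (4747 and 4089), and 2005 for the interaction (0), with 1 RIP knockdown library left. With library weights RIP against input in version 3 knockdown cells gave 2602. Interaction counts were 15, 100 and 137 with DESeq2, and 104 with library weights in version 1.

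Features alike in 3 versions in input (2) were 4 with DESeq2, 66 with library weights (40 up, 26 down), 16 with only the compared groups (11 up, 5 down), and 1 with no filter, equal totals or without the shallow libraries. In RIP (13) they were 59, 0, 1 and 8 with DESeq2, weights, compared groups and no filter, and 63 without the shallow libraries. For RIP against input in knockdown cells (670) they were 1332 with equal totals.

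No pairing of the libraries by replicate number was seen: correlations of deviations between libraries of 1 number lay between -0.194 and 0.178, and in no pair of groups were all 3 over 0.1. With 3 libraries per group this cannot exclude that libraries of 1 number share their origin. With the replicate number as a block, version 3 gave 1 call in input and 235 in RIP, and 1 and 8 features were alike in 3 versions in input and RIP, while all other counts stayed within 1.5 times.

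Without each library in turn, counts for knockdown in input ranged from 251 to 1108, 19 to 277 and 1 to 2 in the 3 versions, and in RIP from 780 to 2870, 598 to 3248 and 166 to 1289. For RIP against input they ranged from 11062 to 12502, 4187 to 7486 and 2748 to 5888 in scramble cells, and from 10145 to 11948, 3240 to 6497 and 2245 to 4842 in knockdown cells. Interaction counts ranged from 0 to 43, 0 to 178 and 0 to 138. Features alike ranged from 1 to 2 in input, 7 to 24 in RIP, 568 to 909 and 475 to 761 for RIP against input. ADAR ranged from -1.43 to -1.38, -1.48 to -1.40 and -1.74 to -1.61 in input, and from -0.84 to -0.71, -1.23 to -1.07 and -1.69 to -1.52 in RIP.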

Other observations

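Several features were near absent from version 3 input and high in RIP of scramble cells, and were picked after their values were seen. KLHL40, a muscle gene, stood at 0.327 ± 0.566 normalized reads in input and 973 ± 676 in RIP, and at 1.56 ± 0.893 and 973 ± 526 in knockdown cells. MRGPRE stood at 0.661 ± 0.761 and 394 ± 397, and PDX1, a pancreatic transcription factor gene, at a mean of 0.170 and 179 ± 149 (mean ± SD, n = 3 each). The satellites HSATI and GSAT stood at 255 and 205 normalized reads in RIP, and MTRNR2L2, a copy of mitochondrial 16S RNA in the nuclear genome, at 521.

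In RIP after knockdown, a few low genes moved far in 1 version and did not pass in the other 2, a difference that was not tested. SLC7A3, an arginine transporter gene, was at least 27.3-fold higher and SLC16A5 at least 30.8-fold higher in version 3, where no RIP scramble library held a read of either (135 ± 143 and 152 ± 98.0 normalized reads in RIP knockdown). Both calls were lost with only the compared groups (limma, adjusted p = 0.388 and 0.354) and with library weights (0.192 and 0.109). ITGA9 went from 0.383 ± 0.663 to 96.9 ± 10.5 normalized reads in version 2 (in version 3 its log2 fold change was 0.72, limma adjusted p = 0.429, and 1.53 without the 3 shallow RIP libraries, 0.0207), and PI15 from 239 ± 99.2 to 1.48 ± 1.38 in version 3. These calls were lost with only the compared groups (limma, adjusted p = 0.206 and 0.342), and that of PI15 with library weights (0.0862).

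The summed share of 7SL and 7SK RNA (RN7SL1, RN7SL2 and RN7SK) was 2.40 ± 0.843% in version 3 input and 0.269 ± 0.226% in RIP (mean ± SD, n = 6).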
